A study of Arabidopsis thaliana with 9 samples.

How the data were processed

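RNA was measured by sequencing in whole seedlings of Arabidopsis thaliana of 3 genotypes, the wild type Col-0 and the mutant lines emb1579-1 and emb1579-3, with 3 libraries each. Per the labels' protocols, seeds were stratified for 3 days on diluted Murashige and Skoog medium and seedlings were collected after 6 days at 20 °C. RNA was taken up with a column kit for plant tissue, and libraries were made with a TruSeq kit, per the labels' protocols. Whether the kit marks the strand is not given in the sources used here. The series' design text calls the libraries of a genotype biological replicates. The p-values of single genes measure the spread between these samples, and those of permutation tests were taken over genes.

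The deposited values were whole-number counts per gene, 1 table of 33602 loci by 9 libraries. The submitters' processing notes name FastQC, HISAT2, Cufflinks and Cuffdiff and the build TAIR10, with no versions and no counting tool. The strand setting and the treatment of reads shared by overlapping or near-identical genes are not given in the sources used here. Without them, values of genes that overlap another gene, or that have a close copy, are uncertain. The table held gene identifiers, and symbols came from the annotation of TAIR10.1, which matched 32835 loci and left 767 without a match. That annotation was used for names, overlap between genes, exon length and the position of EMB1579.

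The columns of Col-0 and emb1579-1 carried the names that the labels give. The remaining 3 columns carried a prefix with another number than the labels give for emb1579-3. They were assigned to emb1579-3 by elimination of names, so they could belong to a line that the labels do not describe. EMB1579 was at the Col-0 level in the libraries labelled emb1579-1, so that wording is kept throughout.

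Totals were 24.1 to 37.5 M counts in 8 libraries and 1.2 M in Col-0 replicate 3. Nuclear genes held 12.5 to 19.0 M counts in the 8 libraries, because chloroplast and mitochondrial genes took 45.8% to 49.6%. Pearson correlations of log2 CPM over nuclear genes were 0.986 to 0.997 between the 8 libraries and at most 0.315 between Col-0 replicate 3 and any other library. Across 5968 genes with 1 opposite-strand neighbour, the Spearman rho with the gene's own count in Col-0 replicate 1 was 0.03 for Col-0 replicate 3 and at least 0.985 for the other libraries. No pair of libraries of 1 group agreed within sampling noise, with chi-square values of at least 3.94 per gene.

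The design fixed before the data were examined put all 9 libraries in 1 fit. After the values of Col-0 replicate 3 were seen, it was left out, and the reported results come from 8 libraries with n = 2 for Col-0 and n = 3 for each mutant line. This departure decides the number of calls, so the counts of the 9-library fit are given beside the reported ones.

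From the deposited counts, edgeR 4.0.16 in R 4.3.3 was run with TMM factors, its default expression filter, robust dispersion estimates and a quasi-likelihood F-test with 1 coefficient per genotype. The filter left 20668 genes. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The common biological coefficient of variation was 0.0904 with 5 residual degrees of freedom. Standard errors (SE) are the absolute log2 fold change divided by the square root of F. Levels are CPM on TMM-scaled totals, given as mean ± SD. The contrast emb1579-3 against emb1579-1 tested the difference between the lines.

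A total of 24 gene lists were written before the data were examined. They were tested with camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over all lists and contrasts. Camera with an estimated correlation and fry were alternatives. None of the camera calls held with an estimated correlation. The list of seed storage and embryo maturation genes had 0 tested members and gave no result. Of the 525 list entries, 504 had their symbol at the same locus in the annotation, and for the other 21 the locus was used as written.

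Named genes followed a rule fixed beforehand. It takes EMB1579, and per mutant line the 6 highest and 6 lowest fold changes among genes past the threshold with a mean of at least 2 CPM, a symbol, and every mutant library on 1 side of every Col-0 library. The same was done for genes changed alike in both lines, and for the 5 highest and 5 lowest between the lines. From each list up to 4 members with the smallest adjusted p were added, with every tested root stem cell niche regulator and the genes FLC, SOS1 and AIF2. The CPM mean was taken over the 8 libraries. The rule gave 137 genes, of which 20 overlap another gene. AT5G05200, AT2G01422, AT3G29633, AT5G35935 and the sulfur deficiency and clock lists were chosen after values were seen.

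The scripts were tested on simulated counts with 200 changed genes per comparison. For emb1579-1 against Col-0, 70.1% of genes changed 1.5-fold, 74.6% of those changed 2-fold and 95.5% of those changed 4-fold were recovered among 20668 genes, with 21 false calls. For emb1579-3 against Col-0 the shares were 67.2%, 83.6% and 95.5%, with 12 false calls. In both comparisons the false calls were a larger share of the genes called than the threshold of 0.05. The simulation changed 200 genes, far fewer than the 3682 and 4193 called in the data, so its error share may not carry over.

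Alternatives were RLE and upper-quartile factors, organelle genes left out, DESeq2 1.42.0, limma-voom, no filter, at least 10 CPM in 3 libraries, only the compared groups, the replicate number as a block, each library left out in turn, and a threshold of 0.01. Added after the data were seen were the subtraction of a background from Col-0 replicate 2 and the removal of genes that overlap another gene. Python analyses used numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.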

Results

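Transcript levels were measured in whole seedlings, roots and shoots together, of the wild type Col-0 and of 2 lines with mutations in EMB1579, a gene also known as RSA1. The series asked what EMB1579 does for the expression of genes of root growth and development. The results rest on 2 Col-0 libraries, 3 libraries labelled emb1579-1 and 3 libraries of emb1579-3. Their totals ran from 24.1 to 37.5 M counts. The counts of Col-0 replicate 3 did not correlate with those of any other library beyond 0.315, and this library was left out. The plot of the 200 highest nuclear genes per library shows 1 property that set it apart.

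**Figure D1:**
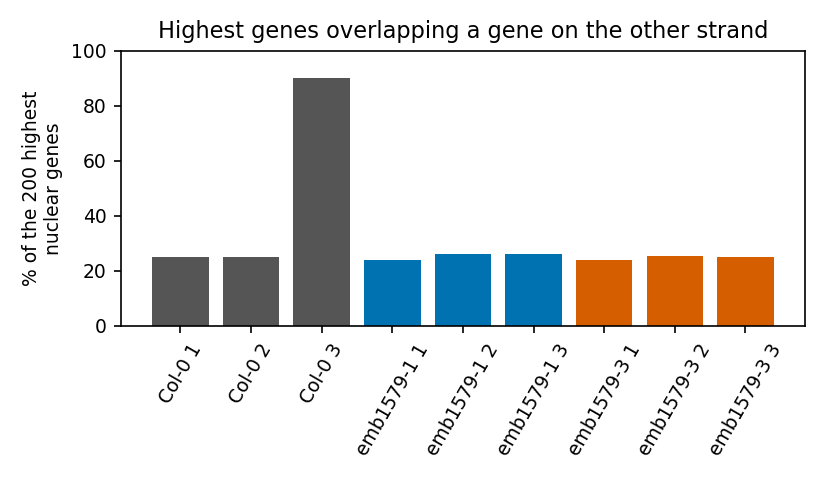
Share (%) of the 200 nuclear genes with most counts that overlap an annotated gene on the other strand, 1 bar per library, coloured by genotype. Col-0 replicate 3 stands at 90%, and the other 8 libraries lie between 24% and 26%.

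EMB1579 (AT2G03150) lies on chromosome 2 from 951888 to 959236 on the plus strand of TAIR10.1, with no overlapping gene. Its transcript was at 48.77 ± 0.24 CPM in Col-0 (SD, n = 2) and at 47.79 ± 1.04 CPM in the libraries labelled emb1579-1 (n = 3). In emb1579-3 it was at 1.44 ± 0.58 CPM (n = 3). The edgeR log2 fold change against Col-0 was -0.03 (SE 0.11, adjusted p = 0.9) for the libraries labelled emb1579-1 and -5.07 (SE 0.15, adjusted p = 6.91e-12) for emb1579-3. Between the lines it was -5.04 (SE 0.15, adjusted p = 2.15e-12). The target transcript therefore does not tell the libraries labelled emb1579-1 from Col-0. The labels give no lesion for either line, and a gene-level count includes transcript with a changed sequence.

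**Figure D2:**
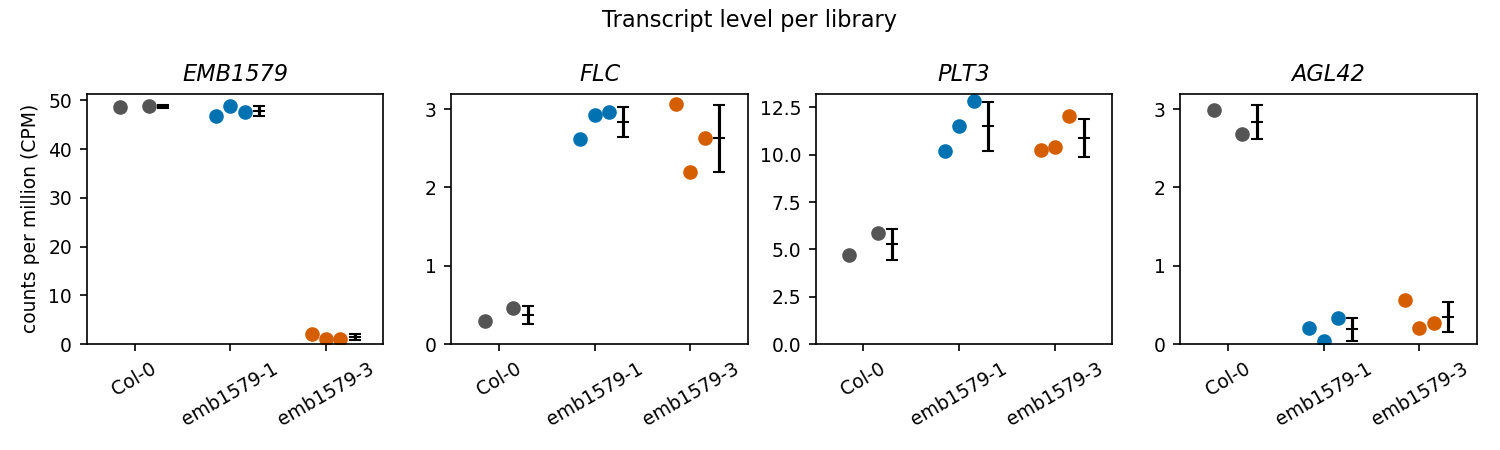
CPM of EMB1579, FLC, PLT3 and AGL42 per library (points) with mean and SD (bars), for Col-0 (n = 2), libraries labelled emb1579-1 (n = 3) and emb1579-3 (n = 3). EMB1579 is low in emb1579-3 only, while FLC and PLT3 are higher and AGL42 is lower in both mutant lines than in Col-0.

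The first comparison set the libraries labelled emb1579-1 against Col-0. Lower were 9 of 16 genes of endodermal barriers and suberin, 7 of 17 of xylem and secondary walls and 7 of 16 of the cytokinin response, and higher were 14 of 22 of the jasmonate response and 8 of 12 of phosphate starvation. These 5 lists passed camera with the preset correlation, and none did with an estimated correlation (adjusted p = 0.15 to 0.22 with an estimated correlation). With fry, which does not set members against other genes, these lists had adjusted p = 0.0074 to 0.016. The defence genes AACT1 and AZI1 rose by 4.16 (SE 0.34, adjusted p = 8.42e-06) and 4.06 (SE 0.50, adjusted p = 0.00496) on the log2 scale. DIN11 rose by 4.21 (SE 0.60), the defensin gene PDF1.3 by 3.41 (SE 0.27), EARLI1 by 3.32 (SE 0.47) and the nitrate transporter gene NRT1.8, which overlaps another gene, by 3.5 (SE 0.37). Among called genes with a symbol and a mean of at least 2 CPM, the lowest were MLP328 at -3.28 (SE 0.52) and its neighbour MLP329 at -2.81 (SE 0.35). TIP2;3, a gene of a tonoplast aquaporin, changed by -2.15 (SE 0.21), ABCA8 by -2.03 (SE 0.23), GulLO2 by -1.91 (SE 0.15) and GSTU9 by -1.91 (SE 0.22). Values of MLP328, MLP329 and PDF1.3 are uncertain where reads match near copies. In all, 1710 genes were higher and 1972 lower by edgeR's quasi-likelihood test at an adjusted p under 0.05. Of these, 342 and 588 changed at least 2-fold. With all 9 libraries, as the design was first fixed, 53 genes were higher and 43 lower, and with at least 10 CPM in 3 libraries 1021 and 1135. Without Col-0 replicate 2 the numbers were 1119 and 1433, and without Col-0 replicate 1 they were 1189 and 3075, each time with a lone Col-0 library.

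The second comparison set emb1579-3 against Col-0. Lower were 11 of 16 barrier, 8 of 17 xylem and 7 of 16 cytokinin genes, and higher were 10 of 22 jasmonate, 8 of 12 phosphate, 6 of 12 iron and 7 of 13 flavonoid genes. These 7 lists passed camera with the preset correlation, and none did with an estimated correlation (adjusted p = 0.15 to 0.52 with an estimated correlation). With fry they had adjusted p = 0.0074 to 0.04. The genes DIN11, AACT1 and PDF1.3 rose by 4.49 (SE 0.59), 3.87 (SE 0.34) and 3.80 (SE 0.26) on the log2 scale. NUDT24 rose by 5.38 (SE 1.09, adjusted p = 0.0253), a call lost when any emb1579-3 or Col-0 library was left out. The lipid transfer protein gene LTP4 rose by 3.60 (SE 0.67) and the phosphatase gene PS2 by 3.48 (SE 0.53). Besides EMB1579, the lowest called genes with a symbol and a mean of at least 2 CPM were MLP328 at -3.17 (SE 0.51), MLP329 at -3.11 (SE 0.36) and the receptor-like protein gene RLP18 at -2.79 (SE 0.27). The laccase gene LAC7 changed by -2.22 (SE 0.24) and the methyltransferase gene IGMT1 by -2.00 (SE 0.16). In all, 2057 genes were higher and 2136 lower by edgeR, of which 356 and 650 changed at least 2-fold. With all 9 libraries 66 were higher and 68 lower, and with at least 10 CPM in 3 libraries 1257 and 1233. Without Col-0 replicate 1 the numbers were 1263 and 3069.

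Genes changed alike in both mutant lines numbered 1293 higher and 1467 lower by edgeR, and 3 genes were called in opposite directions. At least 2-fold in both were 241 and 457. With all 9 libraries 39 and 32 genes were called alike, with at least 10 CPM in 3 libraries 792 and 829, and without Col-0 replicate 1 it was 840 and 2607. The highest and lowest by rule were largely those named above, with NDB4, a gene of a mitochondrial NADH dehydrogenase, at 2.91 (SE 0.63) and 3.48 (SE 0.61). Col-0 levels were low for NDB4 (0.31 ± 0.44 CPM), DIN11 (0.53 ± 0.47), PS2 (0.62 ± 0.42) and NUDT24 (0.43 ± 0.38). For each of them the higher Col-0 value was in replicate 2, which held background counts, so the size of the rise is uncertain. The same held for AACT1 (0.469 ± 0.209 CPM), LTP4 (0.427 ± 0.422), PDF1.2A (0.392 ± 0.281), FLC (0.373 ± 0.118), XTH26 (0.182 ± 0.122) and NAC044 (0.585 ± 0.236). Both comparisons used the same Col-0 libraries. Across genes, which are not independent replicates, the fold changes of the lines had r = 0.851, where simulated groups with no change gave 0.571 over 20 simulations. The covariance was 0.258 against 0.036 in the simulation, a difference of 0.222. Independent lists of these sizes would share 170 higher and 204 lower genes. The 2 Col-0 libraries were not divided between the comparisons, since each would keep 1, and part of the excess may come from sharing them.

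**Figure D3:**
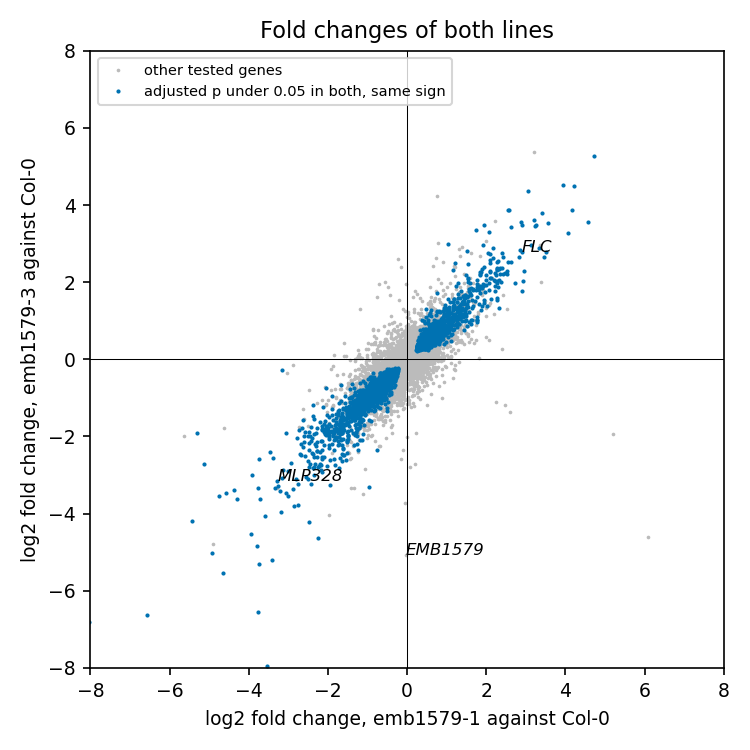
Log2 fold change against Col-0 of each tested gene in the libraries labelled emb1579-1 (x axis) and in emb1579-3 (y axis), with the genes called alike in both in blue and the others in grey. Most blue points lie near the diagonal, EMB1579 lies far below it, and 2 genes lie outside the axes.

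Root stem cell niche regulators, the genes closest to the question of the series, moved both ways. Of 29 listed members, 21 were tested. Of these 21, 3 were higher and 4 lower in the libraries labelled emb1579-1, and 3 were higher and 3 lower in emb1579-3. Adjusted over the list alone, the numbers were 6 and 4, and 4 and 3. The higher members gained that way were PLT2, RBR1 and WOX5 in the libraries labelled emb1579-1 and ACR4 in emb1579-3. The tests named below are adjusted over all genes. The AP2-type gene PLT3 rose by 1.12 (SE 0.14, adjusted p = 1.82e-05) and 1.04 (SE 0.14, adjusted p = 3.43e-05), SCL3 by 0.68 (SE 0.12) and 0.51 (SE 0.12), and MYB56 by 0.89 (SE 0.24) and 1.07 (SE 0.24). PLT3 overlaps another gene. AGL42, a MADS-box gene known from the quiescent centre, changed by -3.92 (SE 0.45, adjusted p = 1.12e-05) and -3.0 (SE 0.40, adjusted p = 4.47e-05). Its level in the lines was 0.189 ± 0.147 and 0.345 ± 0.19 CPM, so the size of its fall is uncertain. Since whole seedlings were sampled, the tissue in which it fell is not known. UPB1, which sets the balance of reactive oxygen in the root tip, changed by -1.20 (SE 0.26) and -1.31 (SE 0.26), and SCL23 by -0.39 (SE 0.13) and -0.45 (SE 0.13). TMO5 fell in the libraries labelled emb1579-1 at -0.51 (SE 0.12) and was at -0.28 (SE 0.12, adjusted p = 0.113) in emb1579-3, a difference that missed the test (adjusted p = 0.575). WOX5, the marker of the quiescent centre, was at 0.14 ± 0.11, 0.49 ± 0.25 and 0.41 ± 0.15 CPM in Col-0, the libraries labelled emb1579-1 and emb1579-3, and its change did not pass the test (adjusted p = 0.0783 and 0.127). PLT1 at 0.12 (SE 0.27) and 0.10 (SE 0.27), PLT2 at 0.86 (SE 0.33) and 0.69 (SE 0.33), SHR at -0.02 (SE 0.12) and 0.29 (SE 0.12), and SCR at 0.04 (SE 0.11) and 0.08 (SE 0.11) did not pass the test. Neither did BBM, JKD, MGP, ACR4, RBR1, RGF3, TPST, TMO7 and NTT in either line. Of all tested genes, 17.8% and 20.3% were called in the same comparisons. The list as a whole did not shift in 1 direction by camera (adjusted p = 0.867 and 0.793). That test cannot decide whether a list whose members move both ways stands apart.

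**Figure D4:**
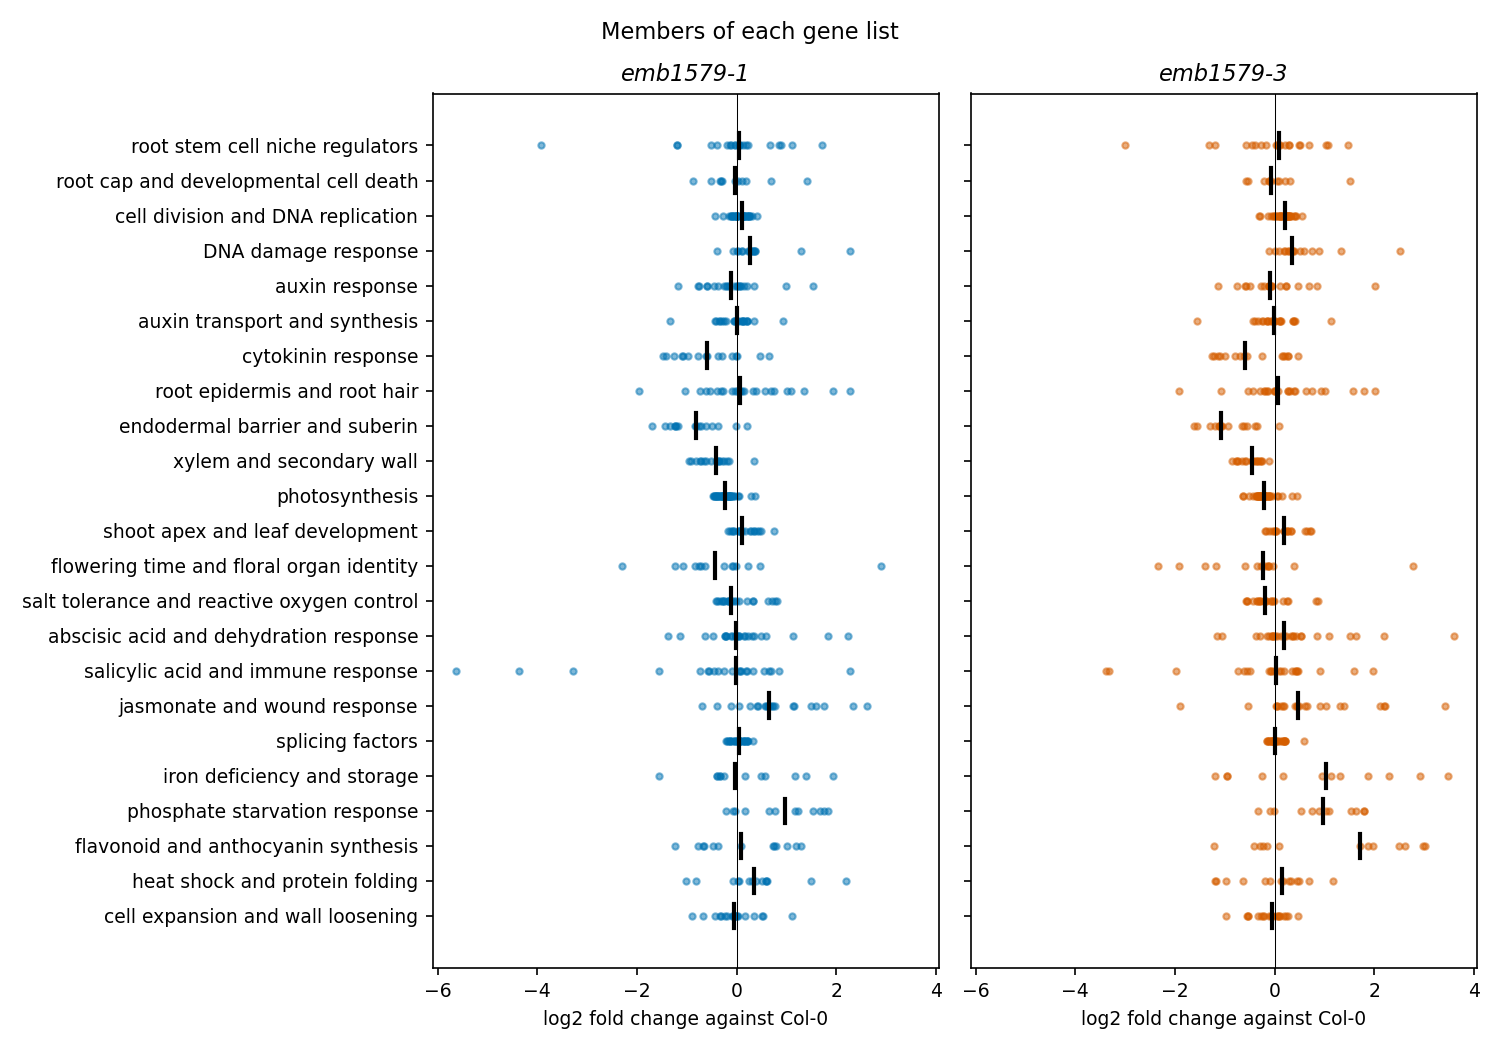
Log2 fold change against Col-0 of each tested member (points) and the median (black bar) of each gene list, for the libraries labelled emb1579-1 (left) and emb1579-3 (right). The endodermal list has medians of -0.82 and -1.07, and the phosphate list has medians of 0.97 and 0.96.

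Endodermal barrier and suberin genes were lower in both lines. Of 16 tested, 9 fell and none rose in the libraries labelled emb1579-1, and 11 fell and none rose in emb1579-3, or 12 and 12 adjusted over the list alone. The suberin genes FAR4, GPAT5 and CYP86A1 changed by -1.69 (SE 0.18), -1.34 (SE 0.18) and -1.23 (SE 0.15) in the first and by -1.62 (SE 0.18), -1.56 (SE 0.18) and -1.3 (SE 0.14) in the second. By camera the list had adjusted p = 1.60e-10 and 3.43e-10, and adjusted p = 0.22 in both with an estimated correlation. Xylem and secondary wall genes fell in 7 and 8 of 17 members with none higher, or 10 and 9 adjusted over the list alone. XCP1, a protease gene of xylem vessels that overlaps another gene, was at -0.66 (SE 0.10) and -0.59 (SE 0.10), and the laccase gene LAC4 at -0.61 (SE 0.14) and -0.78 (SE 0.14). Camera gave adjusted p = 1.61e-04 and 1.55e-04, and adjusted p = 0.19 in both with an estimated correlation. Of 25 root epidermis and root hair genes, 2 were higher and 2 lower in each line, with medians of 0.07 and 0.07, and the counts were the same adjusted over the list alone. RHD2, the NADPH oxidase gene of root hairs, was at -0.73 (SE 0.14) and -0.53 (SE 0.13), and XTH26 at 2.27 (SE 0.55) and 2.02 (SE 0.56). Camera did not separate them from other genes (adjusted p = 0.841 and 0.745).

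Cytokinin response genes fell in 7 of 16 members in each line, with 1 higher in the libraries labelled emb1579-1 and none in emb1579-3. Adjusted over the list alone, 8 and 7 fell. The response regulator genes ARR4 and ARR7 and the receptor gene AHK4 were at -1.10 (SE 0.11), -1.47 (SE 0.19) and -0.77 (SE 0.11) in the first and at -0.80 (SE 0.10), -1.0 (SE 0.18) and -0.70 (SE 0.10) in the second. The camera test gave adjusted p = 8.90e-06 and 4.10e-04, and adjusted p = 0.15 and 0.19 with an estimated correlation. Auxin response genes went both ways, 2 higher and 3 lower, then 3 and 3, of 22. GH3.3, whose product conjugates auxin, rose by 1.53 (SE 0.28) and 2.01 (SE 0.28), and GH3.2 was at -0.75 (SE 0.18) and -0.56 (SE 0.18). Of 23 auxin transport and synthesis genes, 1 was higher and 3 lower, then 3 and 3, with the carrier gene AUX1 at -0.36 (SE 0.08) and -0.39 (SE 0.08) and YUC3 at -1.34 (SE 0.32) and -1.56 (SE 0.32). Adjusted over the list alone, the first had 3 higher and 5 lower, then 3 and 3, and the second 1 and 3, then 3 and 4. Neither auxin list stood apart by camera (adjusted p = 0.823 and 0.973, then 0.807 and 0.934).

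Jasmonate and wound response genes rose in 14 of 22 members in the libraries labelled emb1579-1 and in 10 in emb1579-3, with none lower, or 15 and 10 adjusted over the list alone. AOC1 and AOC2, genes of a jasmonate synthesis enzyme with similar copies, rose by 2.34 (SE 0.20) and 1.15 (SE 0.13) in the first and by 2.22 (SE 0.20) and 1.39 (SE 0.13) in the second. The defensin gene PDF1.2A rose by 2.62 (SE 0.31) and 3.42 (SE 0.29). Camera gave adjusted p = 2.41e-13 and 4.40e-09, and adjusted p = 0.15 in both with an estimated correlation. Phosphate starvation genes rose in 8 of 12 members in each line with none lower, and the numbers were the same adjusted over the list alone. SQD1, a gene of sulfolipid synthesis, rose by 0.65 (SE 0.08) and 0.75 (SE 0.08), and GDPD1, which overlaps another gene, by 1.76 (SE 0.13) and 1.62 (SE 0.13). For this list camera gave adjusted p = 8.03e-10 and 4.40e-09, and adjusted p = 0.19 and 0.21 with an estimated correlation. DNA damage response genes rose in 3 and 5 of 16 members with none lower, or 3 and 6 adjusted over the list alone. NAC044 rose by 2.28 (SE 0.27) and 2.52 (SE 0.26), and GMI1 by 1.3 (SE 0.13) and 1.33 (SE 0.13). Camera gave adjusted p = 7.32e-03 and 1.32e-04, and adjusted p = 0.72 and 0.52 with an estimated correlation. The first call was lost without Col-0 replicate 1 (adjusted p = 7.48e-02), with at least 10 CPM in 3 libraries (9.84e-02) and with fry (8.57e-02).

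Photosynthesis genes fell in 13 of 42 members with 1 higher, then in 14 with 2 higher, or 20 lower and 2 higher, then 18 and 2, adjusted over the list alone. PSAF was at -0.48 (SE 0.10) and -0.62 (SE 0.10), and PETE2 at -0.45 (SE 0.09) and -0.32 (SE 0.09). Camera gave adjusted p = 6.21e-05 and 1.80e-04, and adjusted p = 0.94 in both with an estimated correlation. The call was lost without Col-0 replicate 1 (adjusted p = 0.381 and 0.495) and with fry (0.167 and 0.182), and turned to higher with all 9 libraries (adjusted p = 1.58e-02 and 1.80e-02). Of 19 shoot apex and leaf development genes, 1 and 2 were higher, among them YAB3 at 0.36 (SE 0.11) and 0.33 (SE 0.11). Adjusted over the list alone, none passed, and camera did not separate the list (adjusted p = 0.385 and 0.448).

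Among 14 flowering time genes, 1 was higher and 3 were lower in each line. FLC, a repressor of flowering, was at 0.37 ± 0.12 CPM in Col-0, 2.84 ± 0.19 in the libraries labelled emb1579-1 and 2.63 ± 0.43 in emb1579-3, a rise by 2.89 (SE 0.28, adjusted p = 1.73e-06) and 2.79 (SE 0.29, adjusted p = 2.06e-06). SOC1 and FT, which promote flowering, were at -1.07 (SE 0.11) and -1.24 (SE 0.42) in the first and at -1.17 (SE 0.11) and -2.34 (SE 0.46) in the second. The salt tolerance genes SOS1 at -0.14 (SE 0.14) and -0.17 (SE 0.14) and AIF2 at -0.04 (SE 0.11) and -0.07 (SE 0.11) did not pass the test. Of 35 cell division and DNA replication genes, none changed in the libraries labelled emb1579-1 and 4 rose in emb1579-3, with MCM5 at 0.40 (SE 0.10) and PCNA1 at 0.54 (SE 0.14). Of 27 splicing factor genes, none passed edgeR's test in either line or between them. SR45 was at 0.33 (SE 0.12) and 0.20 (SE 0.12). The 11 root cap genes held 1 higher and 2 lower, then 1 and 1, with MC9 at -0.51 (SE 0.15) and -0.53 (SE 0.15). The 20 cell expansion genes held 2 higher and 3 lower, then none and 4, with EXPA8 at -0.68 (SE 0.13) and -0.97 (SE 0.13). The 22 salicylic acid and immune genes held 5 higher and 4 lower, then 5 and 3, with ALD1 at -4.37 (SE 0.57) and -3.39 (SE 0.50) and FRK1, which overlaps another gene, at 2.27 (SE 0.29) and 1.97 (SE 0.29). The level of ALD1 was only 0.08 ± 0.11 and 0.161 ± 0.055 CPM in the lines, so the size of its fall is uncertain. None of these 6 lists stood apart by camera, with the lowest adjusted p at 5.43e-02 for cell division in emb1579-3. With p adjusted over the list alone, 2 division genes were higher in emb1579-3, expansion had 3 higher and 3 lower, then none and 4, immune genes had 5 and 6, then 6 and 3, and counts of flowering, splicing and root cap genes were the same.

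Stress and metal lists had mixed members. Of 22 salt tolerance and reactive oxygen genes, 5 were higher and 2 lower, then 2 and 4, with the NADPH oxidase gene RBOHD at 0.78 (SE 0.08) and 0.84 (SE 0.08) (camera adjusted p = 0.513 and 0.69). Of 27 abscisic acid and dehydration genes, 2 were higher and 2 lower, then 6 and 1, with LTP3 at 1.84 (SE 0.37) and 2.2 (SE 0.36) (camera adjusted p = 0.972 and 0.152). Without emb1579-1 replicate 1 its direction turned in the libraries labelled emb1579-1, with a call (adjusted p = 9.02e-03). Adjusted over the list alone, the salt list had 5 higher and 3 lower, then 2 and 5, and the abscisic acid list 2 and 2, then 6 and 1. Of 14 heat shock and protein folding genes, 6 were higher and 1 lower, then 4 and 1, with HSP90.1 at 0.62 (SE 0.10) and 0.49 (SE 0.10). Adjusted over the list alone, 7 and 4 were higher. The camera test gave adjusted p = 3.12e-02 and 0.833, and adjusted p = 0.56 and 0.99 with an estimated correlation. The first call was lost with all 9 libraries (adjusted p = 9.08e-02), with the replicate number as a block (5.15e-02), and without Col-0 replicate 1 (9.14e-02), emb1579-1 replicate 1 (5.65e-02) or emb1579-1 replicate 3 (5.94e-02). Of 12 iron deficiency and storage genes, 3 were higher and 1 lower, then 6 and 1, or 7 higher and 4 lower in emb1579-3 adjusted over the list alone. NAS4, whose product makes nicotianamine, was at 0.49 (SE 0.14) and 1.31 (SE 0.13), and FIT, a regulator of iron uptake, at -1.56 (SE 0.24) and -0.95 (SE 0.23). The list had a camera adjusted p = 0.69 and 3.77e-04, and adjusted p = 0.99 and 0.38 with an estimated correlation. Of 13 flavonoid and anthocyanin genes, 4 were higher and 5 lower, then 7 and 1, or 7 and 3 in emb1579-3 adjusted over the list alone. MYB75, a regulator of anthocyanin synthesis, was at 1.2 (SE 0.35) and 2.51 (SE 0.32). Its list had a camera adjusted p = 0.878 and 9.11e-06, and adjusted p = 0.99 and 0.52 with an estimated correlation.

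The third comparison set emb1579-3 against the libraries labelled emb1579-1. In emb1579-3, 5 of 13 flavonoid and 4 of 12 iron genes were higher, and EMB1579, QQS and RLP18 were lower. The anthocyanin genes UF3GT, DFR, LDOX and AT5MAT differed by 2.35 (SE 0.23), 2.23 (SE 0.27), 1.96 (SE 0.21) and 1.76 (SE 0.24) on the log2 scale. The iron reductase gene FRO2 differed by 1.52 (SE 0.23, adjusted p = 0.0272). QQS differed by -3.96 (SE 0.30), RLP18 by -2.88 (SE 0.25), CYP71B22 by -1.48 (SE 0.17) and the receptor kinase gene CRK30 by -1.11 (SE 0.22). These genes were ranked among those with a symbol and a mean of at least 2 CPM. Some loci without a symbol, chosen after values were seen, differed more. AT2G01422 was at -10.70 (SE 0.70) and AT3G29633 at -7.13 (SE 0.59), while AT5G05200 was at 2.87 (SE 0.08) and AT5G35935 at 2.51 (SE 0.26). Against Col-0, AT2G01422 and AT3G29633 rose by 6.10 and 5.2 in the libraries labelled emb1579-1, from mean levels of 0.094 and 0.056 CPM. In emb1579-3 their means were 0.0 and 0.014 CPM, so the sizes of their differences are uncertain. Of 13 flavonoid genes, 5 were higher and none lower, or 8 adjusted over the list alone (camera adjusted p = 1.04e-27, and adjusted p = 0.15 with an estimated correlation). Of 12 iron genes, 4 were higher and none lower, or 8 adjusted over the list alone (camera adjusted p = 3.31e-11, and adjusted p = 0.15 with an estimated correlation). In all, 86 genes were higher and 83 lower by edgeR, of which 25 and 16 differed at least 2-fold. With all 9 libraries none passed, with 301 genes at an unadjusted p under 0.05, and leaving out single libraries gave 33 to 205 higher and 28 to 145 lower. On the 8 libraries DESeq2 called 133 higher and 136 lower, no filter on low counts gave 279 and 290, and at least 10 CPM in 3 libraries gave 55 and 49.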

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

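The tests of the share of genes that overlap on the other strand, of low depth, of background counts, of root tissue share, of clock phase and of splits of the mutant libraries were chosen only after the result was seen.

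Col-0 replicate 3 was in none of the reported comparisons of 8 libraries, and a signal in it stood far above that in the other libraries. Of its 200 highest nuclear genes 90% overlap a gene on the other strand, against at most 26% elsewhere, and 78 nuclear genes with 100 or more counts were at 0 in the other 8 libraries. All 78 overlap a gene on the other strand, against 18.8% of all nuclear genes. Low depth alone is argued against, since expressed genes with no opposite-strand neighbour kept a median of 0.109% of their Col-0 replicate 1 count where the nuclear totals stood at 2.51%. Counting of reads on the opposite strand could account for these values but was inferred from them, and the test fixed beforehand missed its bound of 0.2, with rho 0.207 for the neighbour and 0.03 for the own gene, a difference of 0.178, so it stays open and no biological explanation was tested.

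Genes changed alike in both lines were weighed because both share 2 Col-0 libraries. Background counts in Col-0 replicate 2 are argued against, as 94.8% of these genes kept both calls after its subtraction. A lower share of root tissue was tested by the medians of root hair and endodermal genes, which differed by 0.97 on the log2 scale (permutation of genes, p = 0.00074). An equal fall of both lists is argued against. The root hair genes went both ways, with 2 higher and 2 lower in each line, so they may not track root tissue. A changed share or make-up of root tissue therefore stays open. Another clock phase at harvest may contribute and cannot be told apart from an effect of the lines. Medians of morning and evening clock genes differed by 0.76 on the log2 scale (permutation of genes, p = 0.0029), and values of several of them were seen first. Both permutations shuffled genes, which are not independent replicates, so their p-values do not measure the spread between samples. A difference between the lines and Col-0 in EMB1579 function stays open, as untested.

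The count of genes that differ between the lines was compared with other splits of the 6 mutant libraries. Of 10 splits, 1 gave as many genes, the real one with 169, and the highest of the others gave 1. With 10 splits the share cannot fall below 0.1, so chance stays open by this test.

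Genes named by the rule were marked where emb1579-3 differed from the libraries labelled emb1579-1 in edgeR's test of the difference. EMB1579 (-5.04), QQS (-3.96), RLP18 (-2.88), CYP71B22 (-1.48), CRK30 (-1.11), WRKY40 (-0.691), ZAT10 (-0.557), JAZ6 (-0.488), CAT3 (-0.458) and XTH4 (-0.451) were lower in emb1579-3 than in the libraries labelled emb1579-1 on the log2 scale. UF3GT (2.35), DFR (2.235), LDOX (1.96), AT5MAT (1.76), FRO2 (1.52), BHLH101 (1.31), MYB75 (1.309), CYP71A13 (1.255), BHLH39 (1.14), UGT75C1 (0.964), NAS4 (0.824), KIN2 (0.584) and TSO2 (0.412) were higher. CYP71A13, WRKY40, BHLH101, UGT75C1 and TSO2 overlap another gene.

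Of the gene lists, 8 differed between the lines by camera. Higher in emb1579-3 were flavonoid synthesis (adjusted p = 1.04e-27), iron (3.31e-11), abscisic acid (4.10e-04), cell division (2.34e-02) and DNA damage (2.56e-02). Lower were heat shock (2.30e-04), salt tolerance and reactive oxygen (4.79e-04) and jasmonate (3.12e-02). Few single members passed edgeR's test outside the flavonoid and iron lists. None did for cell division or heat shock, and 1 of 27 abscisic acid and 1 of 16 DNA damage genes were higher. Of 22 salt genes 4 were lower, and of 22 jasmonate genes 3 were lower, or 8 lower and 3 higher adjusted over the list alone. With an estimated correlation the adjusted p was 0.15, 0.15, 0.88, 0.99 and 0.86 for the first 5, and 0.28, 0.54 and 0.54 for the others. Flavonoid and iron calls held under every other setting tried for lists. The other 6 were also lost with fry (adjusted p = 0.0706 to 0.648). Leaving out emb1579-1 replicate 1 turned the direction of cell division (0.711) and jasmonate (0.524) and ended the calls of salt tolerance (0.118) and DNA damage (0.169). The abscisic acid call was lost without emb1579-1 replicate 2 (0.251) or 3 (0.0524). With at least 10 CPM in 3 libraries cell division (0.263), DNA damage (0.22), heat shock (0.158) and jasmonate (0.141) were lost, and without overlapping genes cell division (0.091), DNA damage (0.141) and jasmonate (0.0857). Of the 8 single libraries left out in turn, DNA damage and jasmonate each lost the call in 5, at up to 0.467 and 0.524, cell division in 3, at up to 0.711, abscisic acid in 2 and salt tolerance in 1. Jasmonate was also lost with all 9 libraries (0.109) and with no filter (0.0743).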

How the results depend on the processing

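The fit of 8 libraries, the subtraction of a background from Col-0 replicate 2 and the removal of genes overlapping another gene were chosen only after the data were seen; all other settings were fixed before the data were examined. The cause was not tested for any change below unless a reason is given. With all 9 libraries 53 genes were higher and 43 lower in the libraries labelled emb1579-1, 66 and 68 in emb1579-3, 0 and 0 between the lines, and 39 and 32 alike in both lines, and the fold change of EMB1579 between the lines, at -5.05, lost its call. Directions turned there for PSAF (0.094) and PSAN (0.143) in the libraries labelled emb1579-1, PETE2 (0.128 and 0.250) and GAPB (0.148 and 0.299) in both lines, PAP17 (-2.335 and -2.224) and UGT75C1 (-4.626 and -3.665) in both, and CYP71A13 (-2.80), AT5G05200 (0.227), GI (0.135), LUX (0.023) and PRR5 (0.017) in emb1579-3. The photosynthesis list turned to higher at adjusted p = 1.58e-02 and 1.80e-02.

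With at least 10 CPM in 3 libraries, which tests fewer genes, counts were 1021 and 1135, 1257 and 1233, 55 and 49, and 792 and 829 in the same order. At an adjusted p under 0.01, a stricter threshold, they were 895 and 1090, 1096 and 1158, 37 and 34, and 661 and 786. Between the lines DESeq2 gave 133 and 136 and no filter gave 279 and 290. Past the threshold were 8, 9 and 8 gene lists as reported and 0, 0 and 0 with an estimated correlation. Between the lines fry gave 2, at least 10 CPM gave 4 and removal of overlapping genes gave 5.

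Leaving out each library in turn gave 1119 to 2010 higher and 1365 to 3075 lower for the libraries labelled emb1579-1, 1263 to 2510 and 1490 to 3069 for emb1579-3, 33 to 205 and 28 to 145 between the lines, and 840 to 1531 and 1091 to 2607 alike in both. Where it left 1 Col-0 library, that library was assumed to vary like the other groups. EMB1579 ranged from -0.046 to -0.015, -5.464 to -4.902 and -5.431 to -4.873. List numbers ranged from 6 to 9, 9 to 10 and 5 to 8. The highest counts between the lines, 205 and 145, came without emb1579-1 replicate 1. Its chi-square per gene was 9.87 and 8.19 against replicates 2 and 3 of its group, and 8.79 to 11.96 against emb1579-3. Between replicates 2 and 3 of emb1579-1 it was 3.94. Without emb1579-1 replicate 1 the direction turned for the abscisic acid list in the libraries labelled emb1579-1 (adjusted p = 9.02e-03, range 9.02e-03 to 0.974) and, between the lines, for the lists of cell division (0.711, range 2.32e-04 to 0.711), endodermal (3.99e-02, range 3.99e-02 to 0.939) and jasmonate genes (0.524, range 1.41e-03 to 0.524).

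Whether replicate numbers pair the samples stays open. Between the mutant lines, deviations from the group mean correlated at 0.12, 0.02 and 0.10 in same-number libraries. In the other pairs of the lines they correlated at -0.13 to 0.03. With the replicate number as a block the counts were 1689 and 1883, 1930 and 1901, 127 and 123, and 1251 and 1335, and the lists 8, 9 and 9. For the libraries labelled emb1579-1 heat shock was lost under the block (adjusted p = 5.15e-02) and iron was gained, and between the lines cell expansion was gained. Under RLE and upper-quartile factors, organelle genes left out and limma-voom all counts stayed within 1.5 times those reported. Of the genes called alike in both lines 84.7% kept both calls under DESeq2 and 74.6% without overlapping genes. How depth limits genes at low counts was not tested.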

Other observations

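The tests of clock genes and of AT5G05200, the sulfur list itself and the tests of depth were chosen only after the result was seen.

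Of 15 tested sulfur deficiency genes, 10 were higher in the libraries labelled emb1579-1 and 11 in emb1579-3, with 0 and 1 lower. LSU3 rose by 1.78 (SE 0.17) and 1.89 (SE 0.17), SDI1 by 2.08 (SE 0.17) and 1.99 (SE 0.17), GGCT2;1 by 2.19 (SE 0.20) and 2.06 (SE 0.20), and the reductase gene APR3, which overlaps another gene, by 1.14 (SE 0.10) and 1.11 (SE 0.10). The 10 and 11 genes include LSU1, LSU3 and SDI1, which were higher in both lines. These 3 members had been seen before the list was written. The hypothesis of a wider sulfur deficiency response was therefore tested on the other 12. Their larger unadjusted camera p with the preset correlation was 2.13e-09, which met the bound set for this test. With an estimated correlation the unadjusted p was 0.0227 and 0.0185. Lists fixed beforehand with smaller unadjusted p, such as jasmonate genes at 0.0028 and 0.0083, did not pass once adjusted, so the hypothesis does not hold up better than those lists. Clock genes that peak toward the evening fell in 7 and 9 of 9 members, and those that peak in the morning rose in 3 and 4 of 9. ELF4 was at -1.19 (SE 0.09) and -1.12 (SE 0.09), and CCA1 at 0.59 (SE 0.15) and 1.2 (SE 0.14).

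AT5G05200, chosen after its values were seen, was at 104.19 ± 2.78 CPM in Col-0 (n = 2), 11.66 ± 0.64 in the libraries labelled emb1579-1 (n = 3) and 85.56 ± 5.41 in emb1579-3 (n = 3). Its log2 fold change was -3.16 (SE 0.09) in the libraries labelled emb1579-1, where its 10 nearest tested neighbours changed by at most 0.61 in absolute value. It overlaps another gene.

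Genes at 0 in the other 7 libraries of the comparisons held low counts in Col-0 replicate 2. Greater depth is argued against, since 4114 of them kept a count after thinning to the total of Col-0 replicate 1. RNA of another tissue is argued against, since the highest 1% of them, 54 genes, held 6.7% of the counts. Genomic DNA in the library fits, since silent protein-coding genes held 5.1 counts per kb and other silent genes 4.69, a ratio of 1.09, with 2536 and 2813 genes.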
